A study of Arabidopsis thaliana with 4 samples.

How the data were processed

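Messenger RNA levels were measured in rosette leaves of Arabidopsis thaliana on Affymetrix ATH1 arrays, 1-colour oligonucleotide arrays on which each transcript is read by a set of short probes (a probe set). Labelled RNA of 4 samples was hybridised, 1 array each: 2 of the wild type and 2 of a line carrying an antisense construct against AOX1a.

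Per the labels' descriptions, the authors pooled leaf RNA from 7 and 9 plants for the wild-type arrays and from 9 and 8 plants for the antisense arrays, made labelled cRNA with the manufacturer's components, and had signals computed with Affymetrix MicroArray Suite 5.0. The deposited table holds 1 linear signal intensity per probe set and array, for 22810 probe sets, with a lowest value of 0.1. The authors' intensity values had been scaled per array: the mean after trimming 2% at each end was 500.05 for every array and the 4 means differed by 0.0015%. They were therefore not scaled again. Detection calls per probe set were not used here, and the deposited quality sheet gives only the percent of probe sets called present on each array. The sheet also gives a scale factor, a background, a noise value and 2 ratios of 3' to 5' probe sets. Its lines were tied to the samples by the array names in the sheet. All value columns were matched to a sample. Global scaling of this kind sets every array to one average level, so a shift of all transcripts together cannot be seen, and background-adjusted signals of dim probe sets vary widely on the log scale.

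The values were log2-transformed. The 64 Affymetrix control probe sets were left out of the fit and described on their own. Of the other 22746 probe sets, the 40% with the lowest mean log2 value over all 4 arrays were left out, and 13648 were tested. The antisense line was compared with the wild type with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 2 residual degrees of freedom per probe set and 4.25 prior degrees of freedom borrowed from the others. As a description without a model, probe sets were counted whose 4 ratios of an antisense to a wild-type array were all at least 1.5-fold the same way, and both analyses were repeated for the other 2 ways of splitting the 4 arrays 2 against 2. A permutation test of 2 against 2 values cannot give a two-sided p below 0.333, so none is reported for single probe sets. No sequencing depth applies: the number of arrays limits the precision. The 95% interval of a log2 difference reached 0.55 to either side of it in the median, which is a factor of 1.46.

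The fit was tested on simulated data: 20 sets of 13648 probe sets with the mean levels and spread of this comparison, and 200 probe sets changed in each. Of those changed 8-fold 89.5% were recovered, of those changed 4-fold 67.7%, of those changed 2-fold 4.2% and of those changed 1.5-fold none, with 4.2 false calls per set. The spread of the simulated arrays was independent between arrays, unlike that of the real arrays. The recovered shares hold for that independence and for 200 changed probe sets per set, and can be too high where fewer probe sets change.

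Before the data were examined, the test, the filter, the alternatives, lists of genes by function and cell type and a rule for which genes to name were fixed. No table used here pairs the array's probe sets with genes: the reference table gives loci and symbols but no probe set identifiers. The planned value of AOX1a, the planned tests of gene lists and the naming of genes were therefore not carried out, and probe sets are given by identifier, limited to the 2 higher and the 2 lower ones with the smallest unadjusted p among those whose groups did not overlap. Only the control probe sets carry a transcript's name in their identifier. Genome coordinates are not given for the same reason.

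The titles number the arrays 1 and 2 in each group, with nothing in the labels that ties equal numbers together. For that reason it was fixed beforehand not to treat the numbers as pairs. In the data, the deviations of same-numbered arrays (wild type 1 minus 2, antisense 1 minus 2) correlated at -0.42 across the tested probe sets. The quality sheet's background, noise and scale factor did separate the numbers. The alternatives were the number as a replicate block, quantile normalization, median scaling, an offset of 8.1 (the 10th percentile of all values) before the log, no filter and a filter of 60%, eBayes without a trend and with robust estimation, leaving out the 1061 probe sets whose identifier ends in _s_at or _x_at (which can bind several transcripts), a threshold of 0.1, and leaving out each array. Cyclic loess normalization, a crossed pairing as a block and higher fold limits were chosen after seeing the data.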

Results

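Transcript levels were compared between wild-type Arabidopsis and the line AS12, which is the Columbia accession transformed with an antisense construct against AOX1a (At3g22370) under the constitutive 35S promoter of cauliflower mosaic virus. AOX1a encodes an alternative oxidase, an enzyme of the inner mitochondrial membrane that passes electrons from ubiquinol to oxygen outside the cytochrome pathway. Plants of both genotypes were grown in a soil-less mix without fertilizer at 23 °C, under 350 µmol photons per square metre and second for 14 h a day. Leaves were taken 21 days after sowing. Each genotype was measured on 2 arrays, each of RNA from a separate pool of 7 to 9 plants. The p-values therefore rest on the spread between 2 pools per genotype of one growth experiment, combined by limma with spread borrowed from other probe sets. That spread includes the array differences that cross the genotypes, described below. The level of AOX1a itself is not analysed here, because no table used here ties a probe set to a gene. The labels of the 4 arrays could thus not be checked against the targeted transcript.

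Among the transcripts that control probe sets name, those of actin, GAPDH and ubiquitin differed between the genotypes by at most 0.27 log2 units per probe set. Actin, a cytoskeletal protein, was read by 6 probe sets, which lay 0.10 log2 units lower in the antisense line on average (11.64 ± 0.07 against 11.75 ± 0.01 in the wild type, mean log2 signal, SD, n = 2). The individual differences ran from -0.22 to 0.03, and 3 of the 6 had both antisense arrays below both wild-type arrays; by chance 33.3% of probe sets separate the groups in either direction. GAPDH, the glycolytic enzyme glyceraldehyde-3-phosphate dehydrogenase, was read by 5 probe sets with a mean difference of -0.15 (12.39 ± 0.19 against 12.54 ± 0.03, SD, n = 2), and the groups did not overlap in 2 of them. Ubiquitin, the protein tag for degradation, was read by 5 probe sets that differed by -0.06 on average (13.07 ± 0.16 against 13.13 ± 0.004, SD, n = 2), all with overlapping groups. The bacterial and phage transcripts added during hybridisation (bioB, bioC, bioD and cre), which carry no plant signal, differed by -0.07 on average over 18 probe sets, with 14 lower and 4 higher. The mean difference stayed below 0 for all of these under quantile, median and cyclic loess scaling, and shrank to -0.01 for ubiquitin under quantile and cyclic loess. The Bacillus control probe sets (dap, lys, phe, thr and trp) read at most 97.2 on any array, and the 2 probe sets for 25S and 5S ribosomal RNA at most 69.8. With 2 arrays per group no exact test of a single control could pass 0.05.

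Between 55.5% and 57.3% of probe sets were called present, scale factors ran from 4.07 to 4.54 and backgrounds from 47.93 to 53.16, in the quality sheet's values. Background, noise and scale factor each separated the arrays numbered 1 from those numbered 2, while the percent present overlapped. Backgrounds were 48.58 (wild type) and 47.93 (antisense) for number 1, and 51.81 and 53.16 for number 2. Whether equal numbers shared a processing step is not recorded and was not tested. The ratio of 3' to 5' signal, which rises when RNA is degraded, was 1.47 to 1.72 for GAPDH, 3.16 to 4.68 for ubiquitin and 4.11 to 5.40 for actin by the first probe design. Of 6 such ratios (actin, GAPDH and ubiquitin, each by 2 probe designs), 1 separated the genotypes: the second GAPDH design, at 1.17 and 1.28 in the antisense line and 1.08 and 1.12 in the wild type. Another 3 of the 6 were higher in wild type 1 and antisense 2 than in wild type 2 and antisense 1. The first actin and GAPDH designs separated the arrays by number, as background, noise and scale factor did. Actin read 4.74 (wild type) and 5.40 (antisense) for number 1, and 4.15 and 4.11 for number 2. GAPDH read 1.66 and 1.72 for number 1, and 1.47 and 1.57 for number 2.

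The central comparison asked which transcripts differ in leaves of the antisense line under moderate light. Among the lower probe sets a single one stood apart by its size. Probe set 264076_at read 82.5 ± 6.51 in the antisense line and 685.9 ± 13.8 in the wild type (signal, SD, n = 2), a difference of -3.06 on the log2 scale (95% interval -3.55 to -2.56), or 8.33-fold lower. The 2 higher probe sets with the smallest p were 258225_at and 265478_at. Probe set 258225_at read 686.1 ± 71.3 against 157.3 ± 10.5 (SD, n = 2), 4.36-fold higher, with a log2 difference of 2.12 (interval 1.64 to 2.61). Probe set 265478_at read 817.7 ± 179 against 173.5 ± 19.2 (SD, n = 2), 4.67-fold higher, with a log2 difference of 2.22 (interval 1.66 to 2.79). The next lower one, 263320_at, read 1725 ± 38.5 against 3351 ± 438 (SD, n = 2), 1.94-fold lower. None of these passed limma's test after Benjamini-Hochberg adjustment over 13648 probe sets: the adjusted p was 0.054 for 264076_at, 0.21 for 258225_at, 0.22 for 265478_at and above 0.99 for 263320_at. The call for 264076_at lay at the threshold and was gained under 8 of 14 other settings. Among these 8, cyclic loess and a crossed pairing of the arrays were chosen after seeing the data. Leaving out antisense 1 or antisense 2 left a lone antisense array. The rest were quantile normalization, median scaling, the log2 offset and leaving out _s_at and _x_at probe sets. Their adjusted p by limma was 0.047, 0.039, 0.027 and 0.049, and it reached 0.26 with the replicate block. Leaving out 1 array gave 264076_at an adjusted p of 0.0073 without antisense 1, 0.0078 without antisense 2, 0.24 without wild type 1 and 0.16 without wild type 2, with limma borrowing the spread for the lone array. The other 3 probe sets passed under few of 15 settings. For 258225_at and 265478_at these were 2 settings each, leaving out antisense 2 (adjusted p 0.047 and 0.019) and a crossed pairing of the arrays chosen after seeing the data, and their adjusted p reached 0.55 and 0.52 elsewhere. For 263320_at it was the crossed pairing alone (1 setting, adjusted p 0.0497).

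**Figure D1:**
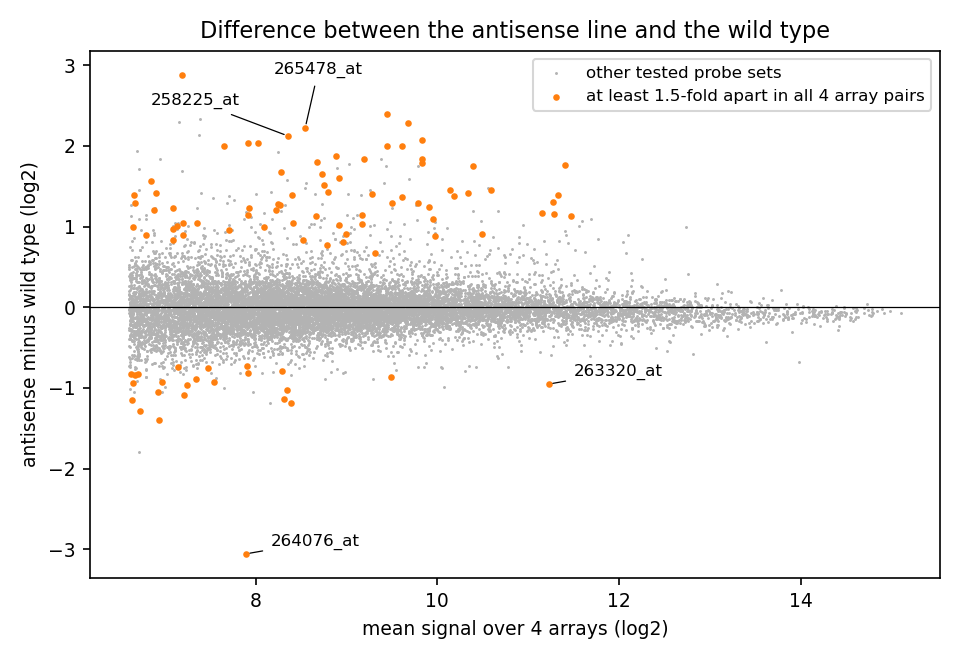
Difference between the antisense line and the wild type (vertical axis, log2) against the mean signal over the 4 arrays (horizontal axis, log2) for the 13648 tested probe sets, 1 point each. Orange points are the 96 probe sets at least 1.5-fold apart the same way in all 4 pairs of an antisense and a wild-type array, 72 of them higher and 24 lower, and the probe set 264076_at lies lowest at -3.06.

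**Figure D2:**
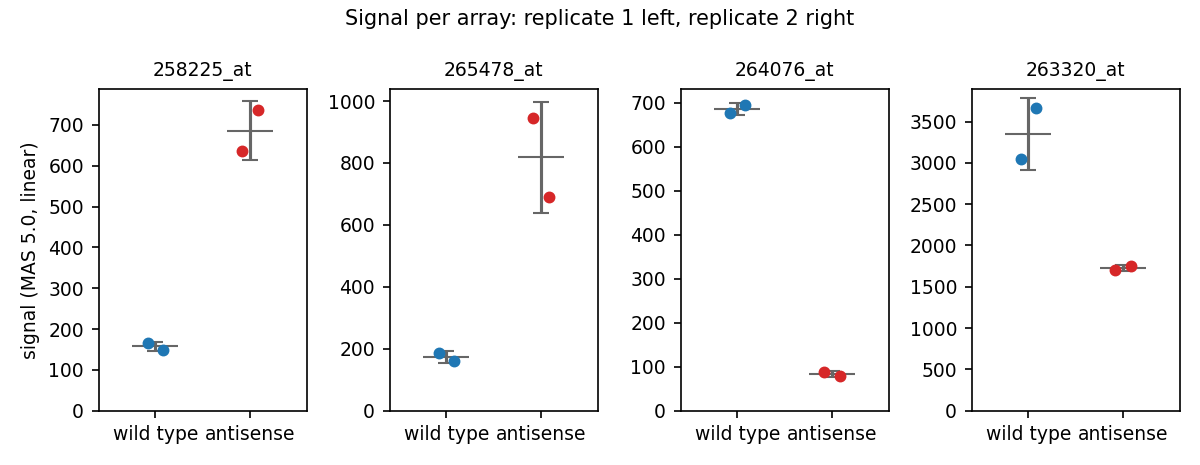
Signal on each array (vertical axis, linear MicroArray Suite signal, a separate scale per panel) for the 2 higher and 2 lower probe sets, with points for the arrays, horizontal bars for group means and error bars for the SD (n = 2). The groups do not overlap in any panel, by the rule that chose these probe sets.

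Across all probe sets, limma called 0 higher and 0 lower at an adjusted p of 0.05. At an unadjusted p of 0.05 there were 379, of which 230 were higher and 149 lower in the antisense line, against 682.4 that chance gives if arrays vary independently. They did not: the same count was 170 for the split by replicate number. It was 2453 for wild type 1 and antisense 2 against wild type 2 and antisense 1. The distance of 379 from 682.4 is therefore no measure of the genotype difference. At an adjusted p of 0.1 the only call was 264076_at. The median difference over all tested probe sets was -0.03 log2 units. Without a model, 96 probe sets were at least 1.5-fold apart in all 4 pairs of an antisense and a wild-type array. Of these, 72 were higher in the antisense line, by a median of 2.46-fold and at most 7.38-fold, and 24 were lower, by a median of 1.91-fold. A 2-fold limit left 23 probe sets, and a 3-fold limit left 3, which were 264076_at, 258225_at and 265478_at. The count rests on the low filter: it was 1029 with no filter and 56 with the lowest 60% left out. With 1 array fewer only 2 pairs remain to be met, and the count was 276 without wild type 1, 479 without wild type 2, 511 without antisense 1 and 708 without antisense 2. In the simulated test, with independent arrays and 200 changed probe sets per set, 4.2% of 2-fold changes were recovered. Most changes of that size would thus be missed even under those conditions, which the real arrays did not meet.

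The spread between arrays of one genotype was as large as that between genotypes. The SD of the log2 difference over the tested probe sets was 0.40 between the wild-type arrays and 0.48 between the antisense arrays, and 0.36 to 0.51 for the 4 pairs across genotypes. The closest pairs crossed the genotypes: wild type 2 with antisense 1 (r = 0.975 across probe sets) and wild type 1 with antisense 2 (r = 0.974), against 0.970 within the wild type and 0.958 within the antisense line. Probe sets are not independent replicates, so these correlations carry no p. The 4 arrays can be split 2 against 2 in 3 ways, and each probe set without ties separates exactly 1 of them, so that chance gives each split 33.3% of the probe sets. The labelled genotypes were separated by 26.8%, the split by replicate number by 23.3%, and the split of wild type 1 and antisense 2 against wild type 2 and antisense 1 by 49.8%. At 1.5-fold in all 4 pairs the counts were 96 for the genotypes, 36 for the split by number and 376 for the crossed split. At 2-fold they were 23, 3 and 38, and at 3-fold 3, 0 and 0. For the crossed split limma called 130 probe sets at an adjusted p of 0.05, where it called 0 for the genotypes and 0 for the split by number. The count at this threshold depends on the scaling: the crossed split had 74 calls under quantile normalization and 0 under cyclic loess, and the genotypes had 1 under each. At an adjusted p of 0.1 the crossed split had 529 calls as deposited, 529 under quantile normalization and 426 under cyclic loess, against 1 for the genotypes under each. The median difference of the 130 probe sets was 0.86 log2 units as deposited and 0.83 under cyclic loess. At 1.5-fold and 2-fold the genotypes thus had fewer probe sets apart than the crossed split and more than the split by number, and at 3-fold more than both. The labels give all 4 arrays the same manufacturing lot, and no batch in them follows the crossed split. The number of plants pooled does follow it: 7 in wild type 1 and 8 in antisense 2, against 9 in each of the others.

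**Figure D3:**
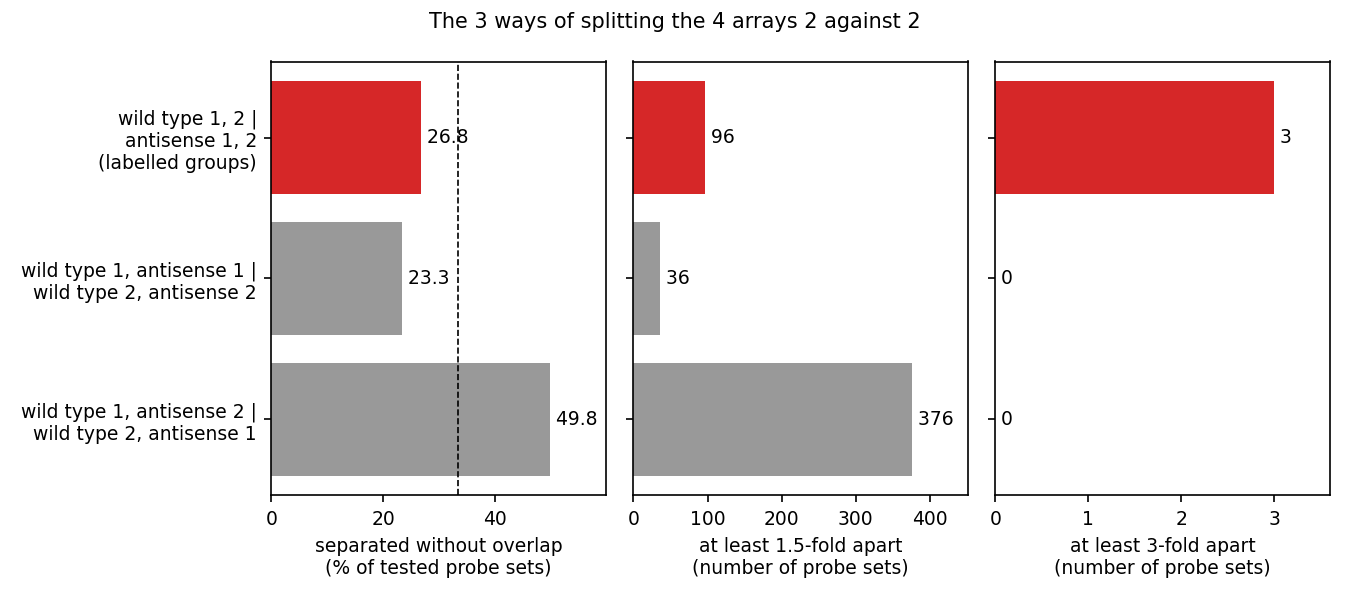
The 3 ways of splitting the 4 arrays 2 against 2 (rows), with the percent of the 13648 tested probe sets that separate each split without overlap (left), and the number of probe sets at least 1.5-fold (middle) and 3-fold (right) apart in all 4 pairs. The dashed line is the 33.3% that chance gives; the crossed split leads at 49.8% and 376 probe sets, and the labelled genotypes hold the only 3 probe sets at 3-fold.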

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

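Where limma called 0 probe sets higher and 0 lower in the antisense line, the replicate block also called 0 and 0, as did no low filter, a 60% filter, eBayes without a trend and robust eBayes. One lower probe set, 264076_at in each case, was called under quantile normalization, median scaling, the log2 offset, cyclic loess, without _s_at and _x_at probe sets and at an adjusted p of 0.1 (1 lower, with 1 higher under the offset alone). Leaving out 1 array gave 0 to 11 higher and 0 to 2 lower, the 11 without antisense 2; a lone array is assumed there to vary like the others. Pairing the arrays crosswise (wild type 1 with antisense 2), added because the deviations of same-numbered arrays correlated at -0.42, called 42 higher and 2 lower. The 96 probe sets at least 1.5-fold apart became 1029 with no filter, 56 with the 60% filter, 23 at 2-fold, 3 at 3-fold, 1 at 4-fold and 276 to 708 without 1 array, where fewer pairs have to be met, and lay between 88 and 102 under the scaling, offset, cyclic loess and cross-hybridisation alternatives. Between 75.0% and 83.3% of them were higher under every scaling. All 4 printed probe sets kept their direction under every alternative that tested them, while 264076_at falls below the 60% filter. With an array left out or a block added, their direction was fixed by the rule that chose groups without overlap, so it is no support. The AOX1a value and the gene lists have no alternatives, as they were not computed. Dim probe sets limit the unfiltered counts; the cause of the other shifts was not tested.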

Other observations

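The tests in this part were chosen after the patterns they bear on were seen; of these, only the count of calls after cyclic loess had not been computed when its test was chosen.

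The quality sheet's column headed actin holds the 3' to 5' ratios of ubiquitin: its values of 4.68, 3.16, 3.45 and 3.82 (wild type 1 and 2, antisense 1 and 2) equal the ubiquitin ratios of the signal table on 4 of 4 arrays within 0.005, and the actin ratios on 0 of 4. The actin ratios from the table were 4.74, 4.15, 5.40 and 4.11. The GAPDH column equals the table's GAPDH ratios on 4 of 4 arrays.

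The pattern most in need of a second look is that wild type 1 and antisense 2 stood together against wild type 2 and antisense 1 (pools of 7 and 8 plants against 9 and 9). Cyclic loess removes differences between arrays that depend on signal level. After it, 49.3% of tested probe sets still separated this split, against 49.8% before and 33.3% by chance. This argues against such differences as the origin of the wide structure, though the test was chosen with that share already computed. The 130 calls fell to 0, which met the condition set beforehand for such differences as their cause. However, the lowest adjusted p (limma) rose only from 0.043 to 0.062. The median difference of those 130 probe sets went from 0.86 log2 units (median SE of a probe set 0.12) to 0.83 (0.11), with all 130 in the same direction. They were picked by this split in these arrays, so their direction is no support. Over all tested probe sets, limma's unadjusted p was under 0.05 for 2453 as deposited and for 2430 after cyclic loess. At an adjusted p of 0.1 limma called 529 and 426. The fall from 130 to 0 was thus a small shift across the threshold. For this split as a whole, these values argue against signal-level differences as the main cause of the calls, although the condition set beforehand was met. RNA integrity stays open: 3 of the 6 ratios of 3' to 5' signal (both ubiquitin designs and 1 actin design) were higher in wild type 1 and antisense 2. The other 3 overlapped on this split. Of those, the first actin and GAPDH designs separated the replicate numbers and the second GAPDH design the genotypes. Chance gives each split 33.3% of ratios without ties, so 6 ratios cannot decide between the splits. An exchange of labels between 1 wild-type and 1 antisense array also stays open, because the targeted transcript could not be read and the values go both ways: the widest gap between groups (7.76-fold, against 2.77-fold in the crossed split and 2.30-fold in the split by number) and the counts at 3-fold (3, 0 and 0) go with the labels, and the counts at 1.5-fold (96 against 376) with the crossed split. A shared tray, harvest or extraction of the crossed pairs is not recorded in the labels and was not tested. Whether the number of plants pooled plays a part was not tested either.

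For the 96 probe sets at least 1.5-fold apart between the genotypes, 2 of the 3 splits of the 4 arrays gave as many, the real one included, and the highest other count was 376; with 3 splits no share under 0.05 can be reached. One hypothesis is that the crossed structure inflates the spread within genotypes and so may hide differences between them: with the crossed pairing as a block limma called 42 higher and 2 lower, and 26 of these 44 were among the 96. That pairing was taken from the same data, so the 44 are no independent evidence of a genotype effect or of this hypothesis, which was not tested.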
